A study of Homo sapiens with 8 samples.

How the data were processed

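HUH7 and PLC/PRF/5 are human cell lines established from hepatocellular carcinoma. The series holds 8 libraries, 4 per cell line: an m6A immunoprecipitate (IP) and an input library from parental cells, and the same pair from cells in which CSTF2 had been knocked out with CRISPR-Cas9. CSTF2 encodes a subunit of the cleavage stimulation factor, which takes part in forming the 3′ ends of mRNAs. MeRIP-seq (m6A-seq) pulls down RNA fragments with an antibody against N6-methyladenosine and sequences them beside an input sample; a region enriched in the IP is called a peak. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was selected with oligo(dT) beads, fragmented and immunoprecipitated, and libraries were primed with random hexamers. Each of the 8 groups held 1 library, so no value had a replicate within a cell line. The 2 cell lines repeat the same comparison, but a spread between libraries would have to come from values per library, which were not analysed here.

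The values analysed were the authors' deposited log2 fold changes, 1 column for HUH7 and 1 for PLC/PRF/5, each beside a column of gene names. Per the file headers, the values are log2 fold changes of a difference; the headers do not say whether the knockout is the numerator or the denominator, and the title of the table names control before knockout without giving the ratio. The sign is therefore reported as deposited throughout ("positive", "negative"), with no direction toward the knockout or the parental cells. Comparisons of signs between the lines assume that both columns use the same direction, which is not stated either. The submitters' processing notes name FastQC version 0.12.0 and genome build hg38. The aligner, the peak caller, the differential test, the scaling between IP and input and any filter are not given in the sources used here. Read counts, peak positions and p-values were not analysed here, so sequencing depth is unknown and no value carries an interval from counts. Analyses planned on them were not run: location of peaks on transcripts, position relative to the last exon and the 3′ end, the DRACH motif, and thresholds on adjusted p-values. The fixed plan for counts, an IP by genotype interaction with the cell line as a block, did not apply.

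Gene names were used as given and brought to current symbols through the RefSeq gene table of GRCh38.p14, by symbol or by a synonym that points to 1 gene. In HUH7, 10127 names were current symbols and 149 matched through a synonym, 98.4% in all. In PLC/PRF/5, 4966 names were current symbols and 158 matched through a synonym, 93.6% in all. The 13 PLC/PRF/5 peaks whose gene name reads as a calendar date, as spreadsheet programs make of some symbols, were kept under the name given. Gene coordinates printed below are those of the RefSeq table, not of peaks.

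The HUH7 column held 1 value per gene, and the PLC/PRF/5 column up to 26 values per gene name, taken as peaks. All values were counted, since no threshold is stated. A PLC/PRF/5 gene was given the median of its peaks, and, for gene lists and counts of genes, a sign when all its peaks had that sign. The comparison of the lines used the median and its sign. An HUH7 value was called repeated when 10 or more genes shared it to 6 decimals and its size was above 1; the other HUH7 values are called unrepeated. Shares of positive values are given with exact (Clopper-Pearson) 95% binomial intervals, which describe the list of genes or peaks and contain no error between libraries. Before the data were examined, 21 gene lists were fixed. The signs of each list's genes were compared with those of all other genes of the column by a two-sided Fisher's exact test, for lists with 5 or more signed genes, with Benjamini-Hochberg adjustment over the lists. Each list's median was also placed among 10000 random lists of the same size from the same column; they could not be matched on expression, which was not analysed here. These tests run across genes of 1 deposited comparison; genes are not replicates, and the tests do not compare the conditions.

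The rule for named genes was also fixed before the data were examined: per sign, the 10 largest values with the same sign in both lines, the 5 genes with the most peaks, CSTF2, and up to 4 members per list. The rule ranked list members by adjusted p; without one, they were ranked by the size of their unrepeated HUH7 value, a change made after the data were seen. Repeated values were not ranked. The correlation of peaks of the same gene was measured as a one-way intraclass correlation with 1000 permutations (one-sided) and a bootstrap over genes, the share of genes with peaks of 1 sign against 10000 permutations (one-sided), the evenness of values by a Kolmogorov-Smirnov distance with Monte Carlo p, and likeness of the cell lines by correlations and same-sign shares over shared genes with 10000 permutations (two-sided). Alternatives tried were a minimum absolute log2 fold change of 1, counting genes for peaks, leaving out chromosome X, leaving out repeated values, and other ways to give a gene 1 value.

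The tests were tested on simulated data. With 10447 genes and lists of 50, the list test called 99.5% of lists simulated with 0.9 of their genes positive, 52% of those with 0.75, and 6% of unchanged lists. The simulation held fewer lists than were tested in each line, and most of its lists were changed. Several of the real lists had far fewer than 50 signed genes. The power of the list tests as run was therefore not measured and may be lower than these shares. On the PLC/PRF/5 peak structure, simulated intraclass correlations of 0.2 and 0.5 were estimated as 0.2005 and 0.4997. The evenness test rejected 100% of simulated normal columns and 4% of even ones. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.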

Results

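m6A MeRIP-seq was performed on parental and CSTF2-knockout cells of 2 hepatocellular carcinoma lines, HUH7 and PLC/PRF/5, to follow changes in RNA methylation after loss of CSTF2. Each of the 8 groups (cell line, genotype, IP or input) held 1 library, so no value had a replicate. The authors' deposited table gave 1 log2 fold change for each of 10447 genes in HUH7 and for each of 9516 peaks in 5477 genes in PLC/PRF/5, and the gene values below are the authors' unless a median is named. Protein-coding genes made up 10237 of the names in HUH7 and 4835 in PLC/PRF/5, where 108 lncRNA and 178 pseudogene names were also present. The direction of the ratio is not stated. As labelled, positive and negative values of a column mark differences between the genotypes of opposite kinds. Whether the PLC/PRF/5 values do so at the gene beside them stays open, as set out below.

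CSTF2 itself (chromosome X, 100820391 to 100841520, GRCh38) had 1 peak in PLC/PRF/5 with a log2 fold change of -0.50 in the authors' deposited table. It was not listed in HUH7. As labelled, the value belongs to the m6A comparison of the genotypes, and it is no check of the knockout. Whether the PLC/PRF/5 values are tied to the gene beside them stays open, as set out below. The paralogue CSTF2T had 0.39 in HUH7 and 2.45 in PLC/PRF/5 in the authors' deposited table. Of the other subunits of the cleavage stimulation factor, CSTF1 was given 0.25 in HUH7 and CSTF3 had peaks at 0.65 and 8.27 in PLC/PRF/5 in the authors' deposited table.

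In HUH7, most genes carried small changes, with more positive than negative values. Positive values were found for 6353 genes, negative values for 4088 and a value of 0 for 6, so that 60.8% of signed genes were positive (Clopper-Pearson 95% interval 59.9 to 61.8). The median over all genes was 0.20, with an interquartile range of -0.36 to 0.87. An absolute log2 fold change of 1 or more was reached by 2324 positive and 1529 negative genes. The median was 0.67 among positive and -0.62 among negative values. Without the repeated values described below, 1833 positive and 705 negative genes reached an absolute log2 fold change of 1 or more.

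The extremes of the HUH7 column stood apart from the rest. A total of 1315 genes (12.6%) held 1 of 16 repeated values, 491 of them between 9.50 and 11.24 and 824 between -9.27 and -7.53. The remaining 9132 genes ran from USP48, a deubiquitinase gene, at -5.18 to CNTNAP2, a neurexin-family gene, at 7.92 in the authors' deposited table, and both were chosen after their values were seen. The CNTNAP2 value is held by too few genes to be called repeated, but it falls on the same series as the positive repeated values, as set out below. Of these genes 5862 were positive and 3264 negative, or 64.2% positive (95% interval 63.2 to 65.2), while the repeated values were more often negative. Repeated values belonged, among others, to the m6A reader YTHDF1 (10.50), the smooth muscle marker ACTA2 (9.92) and the endothelial marker CDH5 (-7.94) in the authors' deposited table, 3 genes chosen after their values were seen.

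**Figure D1:**
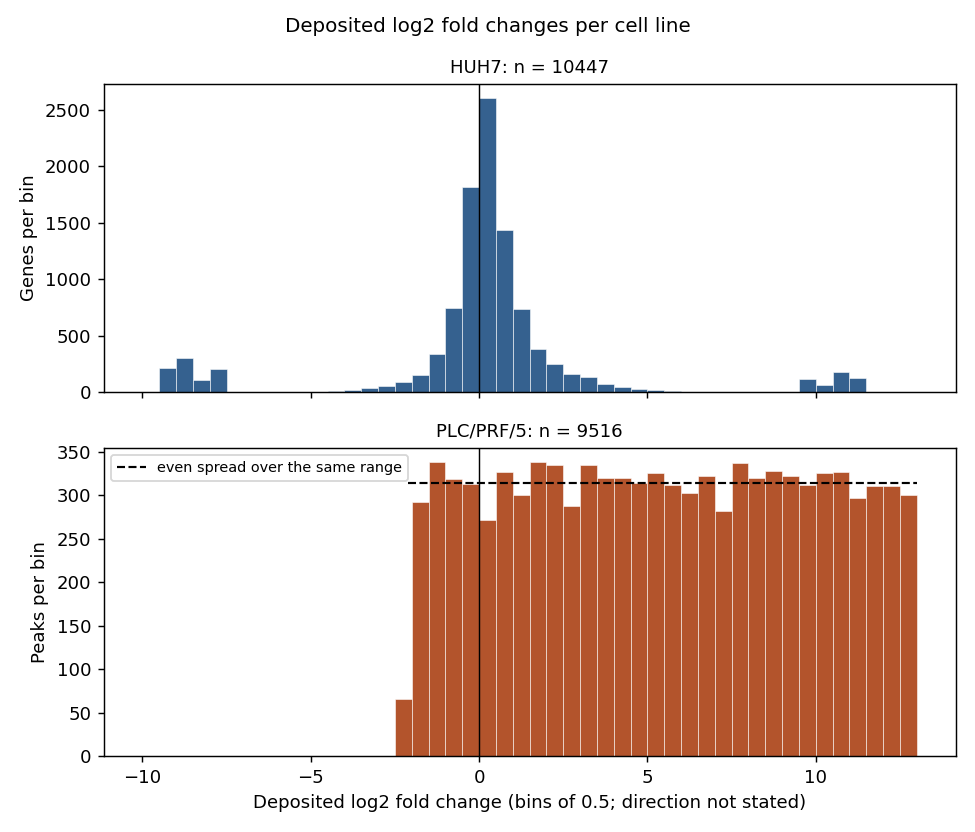
Number of genes (HUH7, upper panel) or peaks (PLC/PRF/5, lower panel) per bin of the deposited log2 fold change; the dashed line is an even spread over the PLC/PRF/5 range. HUH7 values centre near 0 with separate groups beyond -7.53 and 9.50, while PLC/PRF/5 values fill the range from -2.12 to just under 13 at a near constant height.

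MMS22L, a replication fork repair gene, had the largest unrepeated HUH7 value among genes positive in both lines, at 5.77 in the authors' deposited table. The zinc finger genes ZBTB34 (5.34), ZNF397 (5.17), ZNF264 (5.06), ZMYM5 (4.72) and ZNF546 (4.60), the neuropeptide receptor gene NPFFR2 (4.72), the anion channel gene LRRC8B (4.39), the chromatin remodelling gene BPTF (4.32) and CNST (4.17) followed in the authors' deposited table. AIMP1, a component of the tRNA synthetase complex, had the largest unrepeated HUH7 value among genes negative in both lines, at -4.30 in the authors' deposited table. SPA17 (-3.94), RSRP1 (-2.69), the glucuronosyltransferase gene UGT1A6 (-2.65), ZNF766 (-2.44), BPGM (-2.35), ARF4 (-2.31), ATPAF1 (-2.17), ZMYM1 (-2.14) and the amino acid transporter gene SLC7A5 (-1.93) followed in the authors' deposited table. UGT1A6 shares exons with the other UGT1A genes, so its reads cannot be given to it alone. For all of these genes, the same sign in PLC/PRF/5 is no support from a second line. Over all shared genes the same-sign share, 56.8%, was that of permuted signs (mean 56.6%).

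Replication-dependent histone genes and markers of cell types other than hepatocytes had the highest medians of the lists in HUH7. Of 20 listed histone genes, 13 were positive and 7 negative, and 14 had an absolute log2 fold change of 1 or more. Their median was 1.83, above those of all 10000 random lists of the same size, and the 15 unrepeated values had a median of 2.34 (interquartile range -0.12 to 3.12). H2BC9 (5.79), H3C10 (5.09), H2AC13 (4.28) and H2AC16 (3.22) had the largest unrepeated values in the authors' deposited table. H2BC4 (-0.56) and H3C6 (-0.53), chosen after their values were seen, were the lowest of the unrepeated values in the authors' deposited table. Of the 11 listed markers of other cell types, 8 had an absolute log2 fold change of 1 or more, and their median was 0.92, at percentile 97.3 of random lists of the same size, not adjusted for the 21 lists. The share of positive histone genes, 65.0%, was not shown to differ from the 60.8% of other genes (Fisher's exact test, p = 0.821, adjusted p = 0.821). On chromosome 6, where histone genes cluster, lie 17 of the 20, and near-identical copies can share reads. In PLC/PRF/5 only the linker histone genes H1-5 (-2.0), H1-2 (0.15) and H1-4 (1.03) of this list were present in the authors' deposited table.

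Lists of genes of RNA methylation and of mRNA synthesis had medians near that of the HUH7 column as a whole. Members of every HUH7 list were ranked among unrepeated values only. The m6A machinery had 22 positive and 11 negative genes with a median of 0.26. METTL3 (0.42), METTL14 (0.27), FTO (0.46) and ALKBH5 (0.67), the core methyltransferase subunits and the demethylases, lay below 1 in the authors' deposited table. FMR1 (4.13), RBM15 (2.08), YTHDC2 (-1.92) and IGF2BP3 (-1.36) had the largest unrepeated values of the m6A list in the authors' deposited table. Farther out lay its repeated values, 1 positive and 1 negative, of YTHDF1 (10.50) and ZC3H13 (-8.27) in the authors' deposited table. Genes of 3′ end processing had 23 positive and 11 negative members, and CTR9 (-2.17), CPSF4 (-2.08), CASP8AP2 (1.66) and CDC73 (1.28) had the largest unrepeated values in the authors' deposited table. Transcription elongation genes had 20 positive and 17 negative members, and LARP7 (2.36), POLR2C (-2.18) and ELL2 (1.25) were among the largest unrepeated values in the authors' deposited table. Splicing factor genes had 37 positive and 18 negative members, with HNRNPF (-2.37), MBNL1 (2.15) and SRSF5 (1.73) prominent in the authors' deposited table. Chromatin regulator genes had 46 positive and 39 negative members, with INO80 (4.14), KAT2A (3.47) and TET3 (2.59) next to BPTF in the authors' deposited table.

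Liver and metabolic genes also went both ways in HUH7. Hepatocyte genes had 49 positive and 26 negative members with a median of 0.21. UGT2B7 (3.89), the apolipoprotein genes APOA4 (3.40) and APOC3 (2.43) and the drug transporter gene SLCO1B3 (-1.76) had the largest unrepeated hepatocyte values in the authors' deposited table. The liver regulator HNF4A (0.18), chosen after its value was seen, lay close to 0 in the authors' deposited table. Genes of cholesterol and fatty acid metabolism had 46 positive and 24 negative members, with ACSL5 (-3.56), ACSL4 (2.80) and CPT1A (-2.40) prominent in the authors' deposited table. Glycolysis and hypoxia genes had 25 positive and 12 negative members, with PDK3 (2.76) and the glucose transporter gene SLC2A1 (2.66) at the top in the authors' deposited table.

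Signalling and growth genes gave medians between 0.03 and 0.24 in HUH7. TGF-beta and BMP genes had 28 positive and 25 negative members with a median of 0.03, and SMURF2 (5.44) and SMAD1 (-2.03) led them in the authors' deposited table. Wnt genes had 29 positive and 26 negative members, led by VANGL2 (3.65) and TCF7L1 (2.99) in the authors' deposited table. Hippo and Notch genes had 29 positive and 24 negative members, led by DLL4 (3.39) and CCN1 (2.68) in the authors' deposited table. Receptor tyrosine kinase, MAPK and PI3K genes had 60 positive and 34 negative members, led by PIK3CD (3.54) and SPRED2 (2.82) in the authors' deposited table. Cell cycle and replication genes had 37 positive and 26 negative members, led by RRM2 (4.11) and ANLN (-4.0) in the authors' deposited table. Immediate early and other short-lived regulators had 47 positive and 24 negative members, led by FOSL2 (-3.39) and MYCN (3.04) in the authors' deposited table. Cytosolic ribosomal protein genes had 14 positive and 12 negative members with a median of 0.04, led by RPL27A (3.31) and RPS19 (-3.04) in the authors' deposited table.

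Zinc finger, p53 and stress genes had the smallest p-values of the lists in HUH7, and none passed after adjustment. Zinc finger genes named ZNF had 231 positive and 179 negative members, 56.3% positive against 61.03% of other genes (Fisher's exact test, p = 0.0630, adjusted p = 0.605). Genes of the p53 response and cell death had 39 positive and 14 negative members, 73.6% positive (Fisher's exact test, p = 0.0661, adjusted p = 0.605). XIAP (-2.56) and SESN2 (1.94) led the p53 and cell death list in the authors' deposited table. Stress and unfolded protein response genes had 44 positive and 17 negative members, 72.1% positive (Fisher's exact test, p = 0.0865, adjusted p = 0.605). GCLM (3.30) and ATF6B (-2.34) led the stress list in the authors' deposited table. Adhesion and extracellular matrix genes had 44 positive and 25 negative members, led by COL1A2 (4.01), COL1A1 (3.97), COL6A1 (-3.54) and COL12A1 (-3.48) in the authors' deposited table. Markers of cell types other than hepatocytes were listed for 11 of 33 genes, 8 positive and 3 negative, among them STAB2 (-3.22) and PDGFRB (2.26) in the authors' deposited table. Fisher's exact test called 0 of the 21 lists, with adjusted p-values from 0.605 to 0.821, and 0 had an unadjusted p under 0.05.

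**Figure D2:**
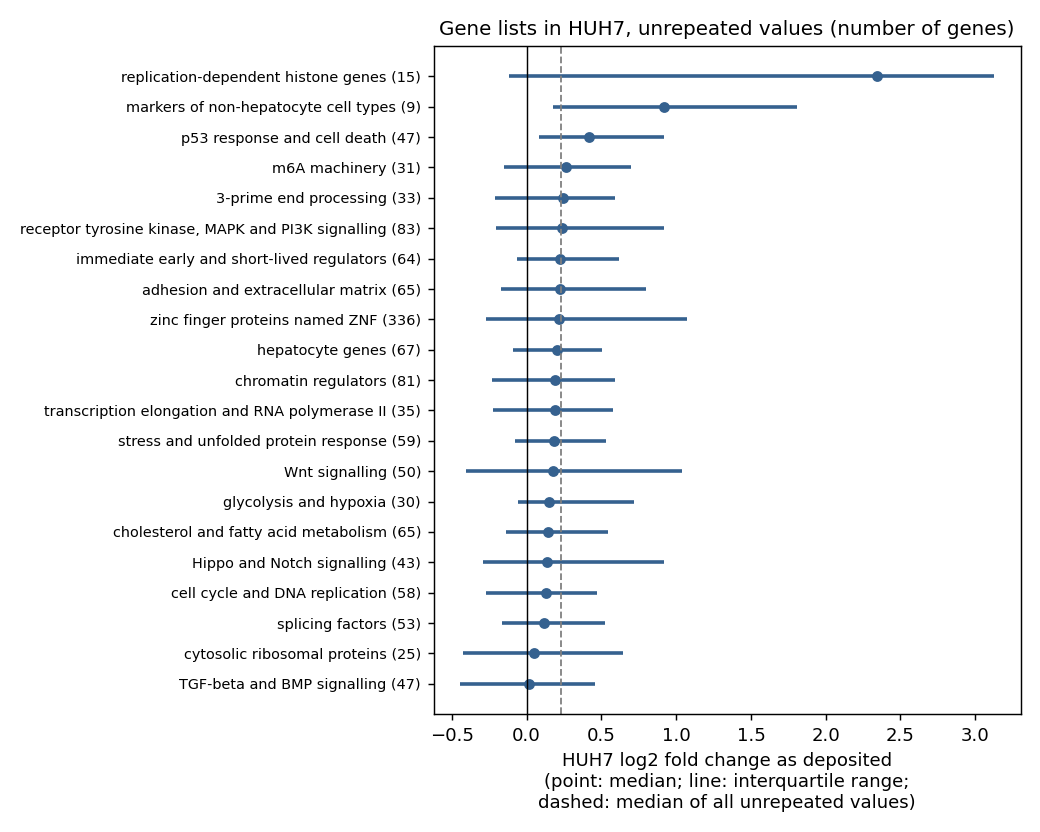
Median (point) and interquartile range over genes (line) of the unrepeated HUH7 log2 fold changes of each gene list, with the number of genes in brackets; the dashed line is the median of all unrepeated values, 0.23. Replication-dependent histone genes have the highest median, 2.34, with a range that spans 0.

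PLC/PRF/5 genes had large values, most of them positive. Of 9516 peaks, 8188 were positive and 1328 negative (86.0% positive, Clopper-Pearson 95% interval 85.3 to 86.7), with a median of 5.44 and an interquartile range of 1.72 to 9.19. By gene, 4279 had only positive peaks, 479 only negative peaks and 719 both. The median was 6.50 among positive and -1.05 among negative peaks. Values ran from -2.12 to just under 13, and each of the 15 unit-wide bins from -2 to 13 held between 599 and 655 peaks. The Kolmogorov-Smirnov distance from an even spread over the range was 0.00559 (n = 9516 peaks, Monte Carlo p = 0.928). For the unrepeated HUH7 values it was 0.377 (n = 9132 genes, Monte Carlo p = 0.001, the smallest that 1000 draws can give). A column spread evenly over the PLC/PRF/5 range would have nearly the same share of positive peaks, medians and quartiles. These PLC/PRF/5 summaries therefore restate the ends of the range and are no separate evidence of a skewed change.

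DST, which encodes a cytoskeletal linker, had the most PLC/PRF/5 peaks, 26, with values from -1.71 to 11.94 in the authors' deposited table. AHNAK had 20 peaks from -0.56 to 12.23 in the authors' deposited table. AKAP9 (-1.91 to 7.42), ASPM (-1.05 to 12.32) and DYNC1H1 (4.42 to 12.40) had 13 peaks each in the authors' deposited table. APOB, the main protein of low-density lipoprotein and chosen after its values were seen, had 11 peaks from -1.48 to 11.40 in the authors' deposited table. Across 5124 genes, which are not independent replicates, the number of peaks rose with gene length (Spearman rho 0.254, Pearson r 0.188, each with permutation p = 0.0001, the smallest they can give). Peaks of the same gene were not shown to be more alike than peaks of different genes, with an intraclass correlation of -0.0154 (bootstrap 95% interval -0.0398 to 0.0108, one-sided permutation p = 0.895). Of the 2166 genes with 2 or more peaks, 66.8% had peaks of 1 sign, within the 66.3 to 69.1% that permuted signs gave.

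**Figure D3:**
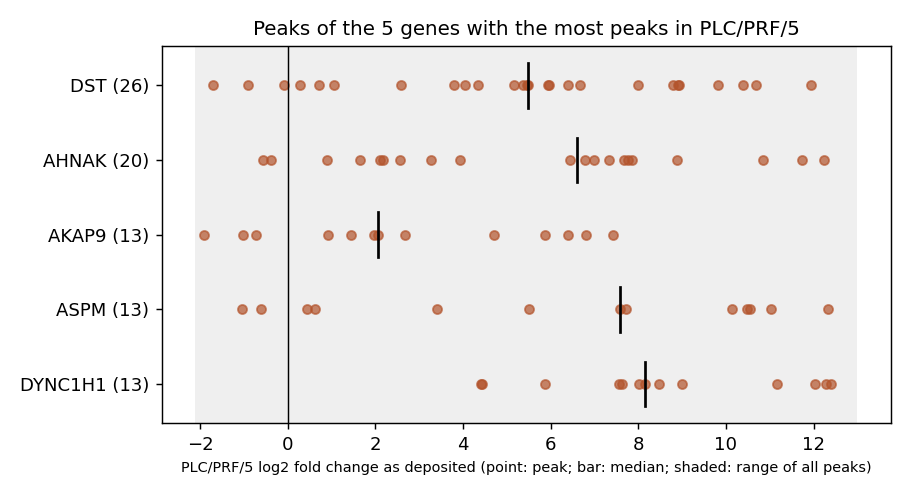
Deposited log2 fold change of each peak (points) and the median (bar) for the 5 genes with the most peaks in PLC/PRF/5, with the number of peaks in brackets; the shaded band is the range of all peaks. Peaks of DST extend from -1.71 to 11.94, over most of that range.

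TPM4, AC073508.2, TLCD2, CTSS, HBP1, PXK, ABCF2, PLA2G12A, CMTM6 and CCDC91 had the largest PLC/PRF/5 peaks among genes positive in both lines, from 12.97 to just under 13 in the authors' deposited table. TPM4 had 0.24 and the cathepsin gene CTSS 2.65 in HUH7 in the authors' deposited table. ZMYM1, DBI, APTX, ETFRF1, ZNF41, FBXW2, PTPN2, TCEAL9, SEMA4B and SLC22A23 had the largest peaks among genes negative in both lines, from -2.11 to -1.95 in the authors' deposited table. DBI had -0.51 and PTPN2 -0.49 in HUH7 in the authors' deposited table. All these peaks lie at the ends of an evenly filled range, so the ranking singles out no gene. The HUH7 values of AC073508.2, PXK, APTX and ETFRF1 were repeated ones. Some genes also had peaks farther from the ends, such as AC073508.2 (0.28), HBP1 (6.85) and CCDC91 (1.03) in the authors' deposited table.

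The 20 gene lists tested in PLC/PRF/5 ranged from 73.3% positive genes for the m6A machinery to 100% for transcription elongation and for adhesion and extracellular matrix, against 89.9% over all genes with 1 sign. Fisher's exact test called 0 of 20 lists, with a smallest adjusted p of 0.649, and 0 had an unadjusted p under 0.05. With 89.9% of signed genes positive, an excess of positive genes could hardly be called in lists of these sizes. Transcription elongation, with 21 positive and 0 negative genes, had p = 0.261 by Fisher's exact test. The absence of calls therefore does not show that lists were without such an excess. The m6A machinery had 11 genes with only positive and 4 with only negative peaks (Fisher's exact test, p = 0.0565, adjusted p = 0.649). Another 11 of its 26 genes had peaks of both signs and were left out. By each gene's peak of largest absolute value, the m6A machinery had 22 positive and 4 negative genes (Fisher's exact test, p = 0.296, adjusted p = 0.804). By peaks, which are not independent replicates, it had 41 positive and 17 negative (Fisher's exact test, p = 0.00196, adjusted p = 0.0393). RBM15 (8.99), ALKBH5 (6.48) and VIRMA (-0.36) were among its members in the authors' deposited table. Immediate early and short-lived regulators had 23 only positive and 6 only negative genes (Fisher's exact test, p = 0.0649, adjusted p = 0.649), and their member MYC had 12.69 in the authors' deposited table. Hepatocyte genes had 29 only positive and 3 only negative members, among them ALB (8.04) and HNF4A (10.94) in the authors' deposited table. Among random lists of the same size, the median of stress and unfolded protein response genes, 7.05, stood at percentile 97.9 and that of 6 markers of other cell types, 0.79, at percentile 0.9, both picked after the percentiles of all 21 lists were seen and not adjusted for their number. Genes of 3′ end processing had 20 only positive and 3 only negative members, transcription elongation genes 21 and 0, and stress and unfolded protein response genes 41 and 2.

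CSTF2 loss was compared between the lines over the 3926 genes with a signed value in each, taking in PLC/PRF/5 the sign of the median of a gene's peaks, also where its peaks differed in sign. The sign was the same in 56.8% of them, against a mean of 56.6% for permuted signs (central 95% of permutations 55.7 to 57.5, two-sided permutation p = 0.714). Of these genes, 2075 were positive in both and 156 negative in both, 1488 were negative in HUH7 and positive in PLC/PRF/5, and 207 the reverse. Across genes, which are not independent replicates, Spearman's rho was -0.00436 (bootstrap 95% interval -0.0355 to 0.0277, permutation p = 0.783) and Pearson's r -0.00307 (permutation p = 0.852). Each line gave 1 comparison without replicates, so a difference between the lines at a single gene was not tested. Same and opposite signs have this meaning only if both columns use the same direction, which is not stated. They also require that the PLC/PRF/5 values are tied to the gene beside them, which stays open.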

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

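The comparisons of same-sign shares between the lines and of the signs of peaks of 1 gene were planned, and the other tests in this part were chosen after the values had been seen. In 1453 of the 3334 genes with 1 sign in each line, the HUH7 value and every PLC/PRF/5 peak had opposite signs; these differences were not tested, since each line had 1 comparison without replicates, and over all 3926 shared genes the same-sign share by the median of a gene's peaks, 56.8%, was that of permuted signs, 56.6%. Among the 34 named list members with 1 sign in each line this held for 13, given below with the HUH7 value before that of PLC/PRF/5, which is the median computed from the deposited peaks where a gene had several (CTR9, FOSL2, HNRNPF, HSP90B1, SOS2 and XIAP). By the values of the authors' deposited table and these medians, negative in HUH7 and positive in PLC/PRF/5 were ATF6B (-2.34 and 12.59), ATM (-3.47 and 5.49), CTR9 (-2.17 and 5.31), FOSL2 (-3.39 and 6.96), HNRNPF (-2.37 and 2.26), HSP90B1 (-2.23 and 7.57), POLR2C (-2.18 and 5.89), RPL31 (-1.11 and 12.13), RPS19 (-3.04 and 1.28), SOS2 (-2.56 and 7.03) and XIAP (-2.56 and 7.46). Positive in HUH7 and negative in PLC/PRF/5 in the authors' deposited table were CDC73 (1.28 and -0.25) and GMNN (3.45 and -1.0). Opposite signs mean opposite changes only if both columns use the same direction of the ratio, which is not stated. They also require that the PLC/PRF/5 values are tied to the gene beside them, which stays open.

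The PLC/PRF/5 column filled its range evenly, ended sharply (47 peaks within 0.1 of the highest value and 55 within 0.1 of the lowest, with 62.9 for an even spread), and peaks of the same gene were not shown to be more alike than others. If the values are what the header says, a change shared by all peaks of a transcript is argued against by the signs. Of genes with several peaks, 66.8% had peaks of 1 sign, which permuted signs also gave. If the column holds another quantity, this share cannot decide on such a change. Ratios of whole numbers against a fixed floor, as the HUH7 ladder would be, are argued against by the 0% of PLC/PRF/5 values repeated 10 times or more. Ratios of other numbers against a floor need not repeat, so this share cannot decide on them. The explanation that the values are not tied to the gene beside them, for example because the column holds another quantity than its header says, predicted an intraclass correlation near 0, and -0.0154 was found (permutation p = 0.895). How the column was made is not recorded in the sources used here. Independent changes at each peak, a biological explanation that was not tested, remain open only for the lack of likeness within genes. Independence alone does not account for the even spread or the sharp ends. The Kolmogorov-Smirnov distance from an even spread was 0.00559, against 0.377 for the unrepeated HUH7 values.

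The 16 repeated HUH7 values lay on a fixed ladder. They equalled a constant (7.92 for positive and 5.94 for negative values) plus log2 of the whole numbers 3 to 10, with a largest deviation of 6e-07, which is what whole numbers set against a fixed floor would give. CNTNAP2, at 7.92, lay on the step of the number 1. No gene had a value between it and the positive step of 3, or beyond the step of 10 of either sign. Among negative values, none lay between the step of 3 and USP48, at -5.18 in the authors' deposited table. Why the ladder spans only 3 to 10, with a constant of its own for each sign, stays open. A lower detectability of these genes is consistent with their lower share with a PLC/PRF/5 peak, 27.5% against 39.1% of other genes (odds ratio 0.590, 95% interval 0.517 to 0.671, Fisher's exact test, p = 1.25e-16). Read counts at the edge of detection would thin out with rising count, but the step of 10 held 1.04 times as many genes as the step of 3 (165 and 158), and why the steps are equally filled stays open, as does a true gain or loss of peaks at these genes.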

How the results depend on the processing

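The fit blocked on the cell line was not run, since it needs read counts per library, which were not analysed here. Leaving out a replicate was not possible, since each group held 1 library. Alternatives that need adjusted p-values, peak-calling p-values, peak positions or counts were not run: stricter adjusted p, merged overlapping peaks, other location, last exon and motif settings, DESeq2, each cell line left out in turn, no block for the cell line, and count filters. Depth is unknown, so what it limits was not measured. With an absolute log2 fold change of 1 or more, HUH7 had 2324 positive and 1529 negative genes, with median sizes of 2.06 and 7.53, since most of the remaining negative values were repeated ones; the share positive was 60.3%. PLC/PRF/5 then had 696 negative peaks and 91.6% positive peaks, and 77.8% of its genes with several such peaks had 1 sign, just below the range of permuted signs (mean 79.3%, 95% range 78.0 to 80.6), whereas without the minimum the share lay within it; the cause was not tested. Counted by gene, PLC/PRF/5 had 4279 positive and 479 negative, 89.9% positive. Leaving out chromosome X gave positive shares of 60.97% in HUH7 and 85.99% in PLC/PRF/5. Among planned settings, the list test called 1 list, the m6A machinery, in PLC/PRF/5 counted by peaks, and 0 with a minimum of 1 in either line; the cause was not tested. The remaining settings were chosen after seeing the data. Without the repeated values, HUH7 was 64.2% positive and shared its sign with PLC/PRF/5 in 58.7% of genes (permuted mean 58.5%); with a minimum of 1 in both lines this was 58.5% (permuted mean 58.2%), so the shares moved together with those of permuted signs. Spearman's rho between the lines stayed between -0.00892 and 0.00829 in the 4 settings tried. The list test called 0 lists in HUH7 without the repeated values and 0 in PLC/PRF/5 by each gene's peak of largest absolute value.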

Other observations

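The tests of explanations and of chromosomes in this part were chosen after the values had been seen. Replication-dependent histone genes had high HUH7 values. The median of the 15 unrepeated values stood at percentile 100 among 10000 random lists, but the list was singled out for its median, and random lists treat genes as independent, which histone copies that share reads are not. Had the copies acted as a single measurement, 5.67% of genes would reach their median, so chance stays open. Ribosomal protein genes did not share the high values, with a median of 0.048 for their unrepeated values (interquartile range -0.43 to 0.64). They each encode a different protein and are not near-identical copies, so multi-copy gene families in general stay open. Wider values of genes without a PLC/PRF/5 peak stay open for the same reason as chance. The percentile among lists of such genes was 100, with a highest median of 1.68. Singly, however, 7.01% of these genes reach the histone median. Reads shared among the histone copies themselves, poly(A) selection that leaves few of these RNAs in the library, and a change in RNA level or cell cycle that the ratio did not remove may each contribute, as may the knockout itself, whose direction in these values is not stated; none was tested, and the members also went both ways, with H2AC11 and H3C1 on the positive and H2BC8, H2BC11 and H4C14 on the negative repeated values.

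In HUH7 the share of positive unrepeated values differed between chromosomes (permutation p over genes 0.0001, the smallest that can be given), from 55.5% on chromosome 10 to 75.3% on chromosome 21 and 72.6% on chromosome 22. Over the 23 chromosomes it correlated with the density of protein-coding genes with a Spearman rho of 0.451 (permutation p = 0.0332) and a Pearson r of 0.341 (permutation p = 0.128); without chromosomes 17 and 19, the farthest from the median density, rho was 0.347 (permutation p = 0.126) and r was 0.472 (permutation p = 0.0308), so the relation depended on the measure. Neighbouring genes showed a rank correlation of 0.000385 (permutation p = 0.474).

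The columns differed in form. HUH7 genes ran in chromosome order (96.4% stood next to a gene of the same chromosome, against 5.17% in PLC/PRF/5), with up to 9 decimals against 5. Current names such as H2AC and H2BC genes appeared in HUH7, while 13 PLC/PRF/5 peaks had gene names turned into dates and none in HUH7 did.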
